A study of Mus musculus with 13 samples.

How the data were processed

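The series holds polyadenylated RNA libraries of 100 sorted bone marrow HSCs each, made by Smart-seq2 from WT mice and MEK1-deficient (KO) mice, untreated or after 5-FU. Only the authors' deposited table was used. It gives, for 13 libraries, log2-scale variance-stabilized values made by the authors with DESeq2 and deposited as normalized data, per the submitters' processing notes. The same notes name Trimmomatic for trimming, Bowtie 1.1.1 for alignment and the mm10 genome. The counting tool and the annotation are not given in the sources used here, nor is the strand setting of the counting, and Smart-seq2 does not mark the strand.

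The values were turned back into counts. The value that the transformation gives at exactly 0 was solved as 7.6484, the same for every library. A constant is added to each count before the transformation, so a count of 0 lies above that value. The lowest steps of each library's values fix its size factor and its added constant. Reads recovered this way were whole numbers within 0.1 for 100% of genes in 12 libraries and for 99.9924% in untreated WT D1, whose largest distance was 0.1726 and whose steps show an added constant of 2 instead of 1, such as 2 summed runs give. Read totals were 14174712, 11416753, 16955564 and 25380570 in WT A2, A3, A4 and D4 after 5-FU, and 11947917, 13750777 and 13656119 in KO A5, A6 and A8. In untreated cells they were 45384866, 14232268 and 15289647 in WT D1, D2 and D3, and 17532975, 19942527 and 15544452 in KO D4, D5 and D6. The 10 highest genes held 6.95% to 8.12% of the reads and mitochondrial genes 4.232% to 6.030%. Symbols were taken from GENCODE M21 (GRCm38) for 13054 genes, of which 12260 are protein-coding, and 147 identifiers had no symbol and were kept in the test but not named.

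Genes with a normalized count of at least 10 in at least 3 libraries were tested, 12846 in all, against 11583 with a minimum of 50. The planned filter on the unlogged deposited value would remove nothing, since a count of 0 has a value above it, so the filter was applied to the recovered normalized counts. The deposited values were already on a log scale and were used without a further logarithm. Differences were tested in limma 3.58.1 (R 4.3.3) with one mean per group over all 13 libraries, contrasts, and eBayes with a mean-variance trend (residual df 9, prior df 7.67). P-values were adjusted by Benjamini-Hochberg within each comparison at 0.05. The comparisons were KO against WT in untreated cells and after 5-FU, 5-FU against untreated in WT and in KO, and the genotype by treatment interaction. Map2k1 was also tested with an exact permutation test of the deposited log2-scale values. Recovery and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

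Lists of genes for pathways and cell types, 36 in all, were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and most of the other settings listed below. Of these lists, 35 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01 between genes, again with a correlation estimated per list, and with fry, a rotation test. The p of fry asks whether the genes of a list move on balance one way, and neither of its p-values compares the list with other genes. Camera calls that held with an estimated correlation were 9 lists in KO against WT after 5-FU, megakaryocyte and erythroid genes in the WT response and in the interaction, HSC identity and interferon genes in the KO response, and 0 in untreated cells. Lists described singly were chosen after their results were seen, and the class II histocompatibility and histone lists were drawn up after the data were seen.

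Genes were named by 4 rules. Map2k1 and other genes of its cascade were named in every comparison. Then came up to 8 genes per direction (5 for the interaction) with the largest log2 difference among those that passed, had a mean count of at least 50 in the higher group and no overlap between the groups (this last condition not used for the interaction). The 3 members with the smallest p were named for each list described singly. Where fewer than 5 genes passed, those with the next smallest p were added and are given as not passing. Some genes that these rules name are not reported here.

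The method was tested on simulated data with 200 changed genes among 12846. With 3 against 3 libraries it recovered 29% of 2-fold and 60% of 4-fold changes, and 4 of 93 calls were false. With 4 against 3 libraries it recovered 34% and 69%, and 2 of 105 calls were false. No call had the wrong sign, a raised list was called, and 0 of 40 random lists were. The simulation drew each gene independently, without correlation between genes and without nearly alike libraries. It therefore cannot show how often genes or lists are falsely called where these occur.

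Alternatives were other thresholds, filters and pseudocounts, TMM and quantile scaling, library weights, robust variances, acquisition date as a term, limma-voom on the recovered reads, only the groups of a comparison, WT A3 and D4 after 5-FU averaged into 1 replicate, and each library left out in turn. The exchange of labels within each comparison covered 10, 35, 35, 10 and 100 splits. The edgeR and DESeq2 fits planned for recovered whole reads were not run, and limma-voom was run on the recovered reads instead. TMM factors were computed by own code with trims of 30% (M) and 5% (A). No reads were realigned. The untreated libraries are described with an added technical replicate of WT, which the table does not hold as a separate column.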

Results

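Polyadenylated RNA of haematopoietic stem cells (HSCs), the bone marrow cells that renew themselves and form all blood lineages, was sequenced in 13 mouse libraries. Each library was made from 100 sorted cells by Smart-seq2, a full-length cDNA protocol for very small RNA inputs. The cells came from wild-type (WT) mice or from mice lacking MEK1, the kinase encoded by Map2k1 that activates ERK (KO). The donors were untreated or had received 5-fluorouracil (5-FU), a drug that kills cycling blood cells and drives HSCs into division. The groups held 3 untreated WT libraries (D1, D2, D3), 3 untreated KO libraries (D4, D5, D6), 4 WT libraries after 5-FU (A2, A3, A4, D4) and 3 KO libraries after 5-FU (A5, A6, A8). The series title places the comparisons in a question about how ERK-dependent feedback keeps HSCs from exhaustion. The 5-FU dose and the time of sampling are not given in the sources used here, nor is it stated that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may in part be technical.

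The recovered read totals lay between 11416753 and 25380570 in 12 libraries. Untreated WT D1, sequenced on both flowcells, held 45384866 reads. Between 12093 and 12615 genes had at least 1 read in a library, and 12846 genes were tested. Levels below are normalized counts, recovered from the deposited values, as mean ± SD over the libraries of a group. Changes on the log2 scale are those of the deposited variance-stabilized values, which understate the change of low genes. A count of 3 reads, the limit that a count of 0 allows for counting error alone, corresponded to a normalized count between 0.979 and 4.35.

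The first principal component of the 13 libraries held 21.7% of the variance and separated WT libraries after 5-FU from the untreated libraries. The second held 19.7% and set the 3 KO libraries after 5-FU apart from the rest. On these 2 components untreated WT and KO libraries lay near each other, and on the third (10.3%) untreated WT D1 lay apart from the other 12. WT D4 after 5-FU was nearly a copy of WT A3, with a Pearson correlation across genes of 0.988, against 0.912 to 0.943 for other pairs of the same group outside the KO libraries after 5-FU, whose pairs reached 0.966 to 0.977. A chi-square comparison of their reads gave a median over genes of 4.34, above the 0.455 that sampling alone gives and below the 9.72 to 14.8 of the pairs of KO libraries after 5-FU and the 27.0 to 64.6 of the other pairs of the same group. One cDNA amplified or sequenced again would also exceed sampling noise, so independence of the 2 libraries is not shown. They are counted as 2 in the fit, which makes p-values with 5-FU WT too small if they are one sample. All groups share one residual spread in the fit, so p-values of the comparisons without 5-FU WT tend to be too small as well. The count of genes called in each comparison is also given with the pair averaged into 1 replicate. Cells of untreated libraries were acquired in 2015 and those of 5-FU libraries in 2016, except WT D4 after 5-FU, labelled 2015 and sequenced on the other flowcell.

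**Figure D1:**
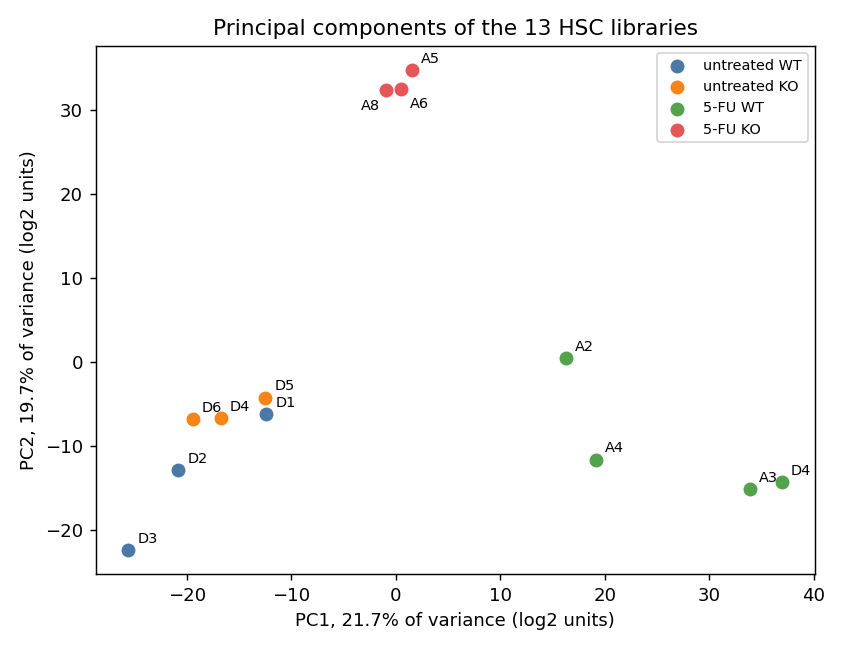
Principal components of the variance-stabilized log2 values of all 13 libraries, 1 point per library and coloured by group, with the share of variance on each axis. The 3 KO libraries after 5-FU form a tight group, A3 and D4 of the 5-FU WT group lie side by side, and A2 lies between the other 5-FU WT libraries and 5-FU KO.

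Map2k1 (ENSMUSG00000004936, chromosome 9, 64185770 to 64253631 on the minus strand, GRCm38/mm10) was lower on average in KO libraries and still detected in each of them. In untreated cells its normalized counts were 905, 1116 and 1766 in WT and 611, 749.8 and 545 in KO. The KO mean was 50.3% of the WT mean (1262 ± 449 against 635 ± 105, SD, n = 3 and 3). The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. After 5-FU the counts were 604, 1634, 584 and 1573 in WT A2, A3, A4 and D4 and 328, 459.9 and 304 in KO, and the KO mean was 33.1% of the WT mean (exact permutation p = 0.0857, with 0.0286 the smallest possible). In limma, Benjamini-Hochberg adjusted, the difference was not called in untreated cells (log2 -0.69, adjusted p = 0.460) and was called after 5-FU (log2 -0.96, adjusted p = 0.0339). The call after 5-FU was lost with the alike pair A3 and D4 averaged, without A3, D4, A5, A6 or A8 in turn, with quantile normalization, with the date term, with limma-voom and with only the 5-FU libraries in the fit. Its log2 difference stayed between -0.78 and -1.15 when single libraries were left out or the pair averaged. Reads from exons left in a deleted allele can remain in such counts, and counts per exon were not analysed here.

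No difference between the genotypes was called for Map2k2 and Mapk3 of the same cascade. Map2k2, encoding the related kinase MEK2, measured 1000.2 ± 301 in WT and 1412 ± 163 in KO after 5-FU (limma adjusted p = 0.206, SD, n = 4 and 3). Mapk3, encoding ERK1, measured 379 ± 156 against 356 ± 56.6 (limma adjusted p = 0.985). In untreated cells the adjusted p values of the 2 genes were 0.635 and 0.826. No interaction of genotype and treatment was called for Map2k1, Map2k2 or Mapk3 (limma adjusted p = 0.793, 0.931 and 0.818), and neither 5-FU comparison called any of the 3.

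**Figure D2:**
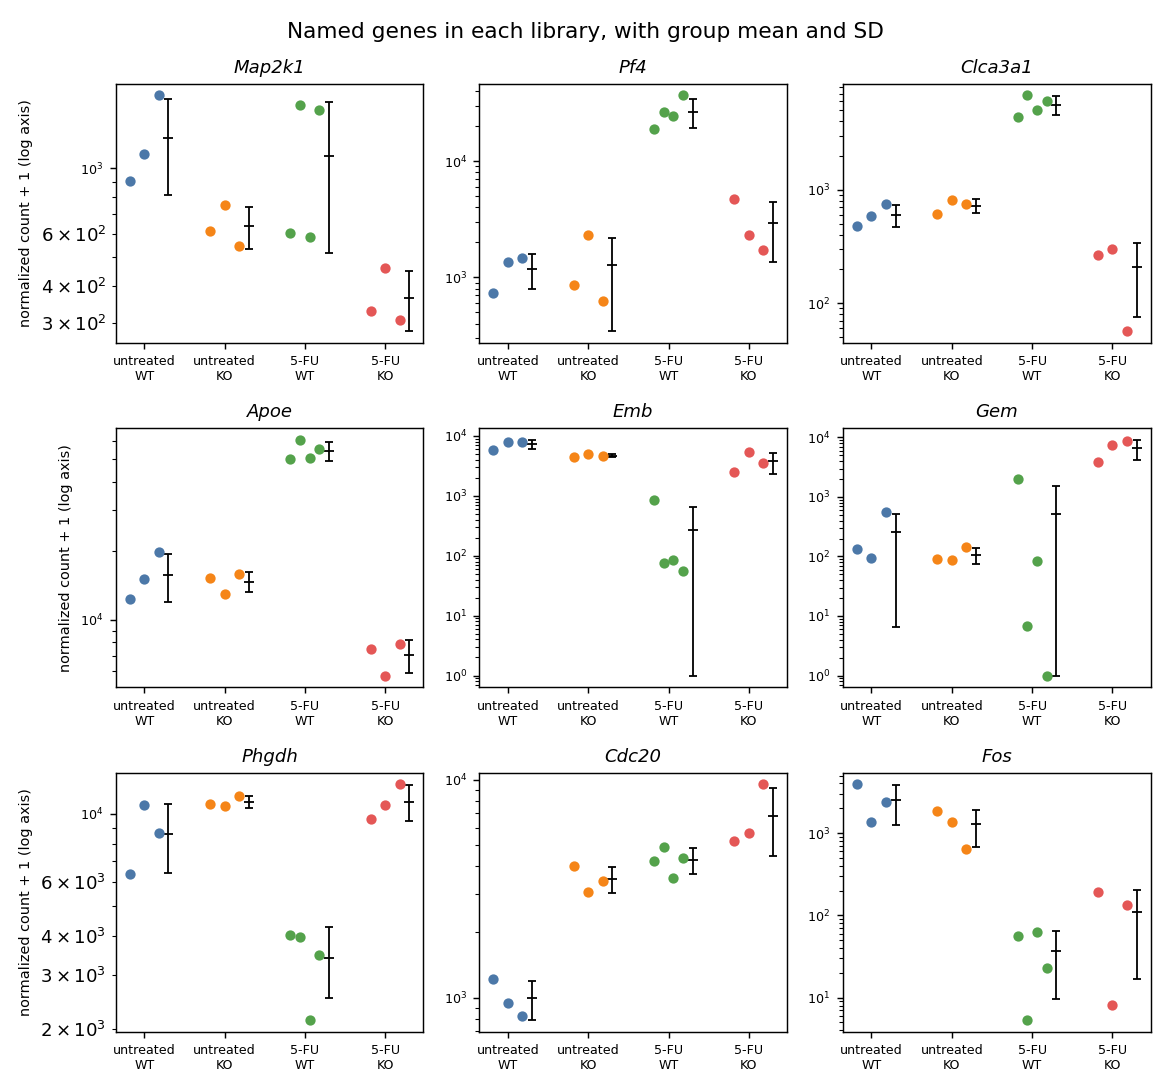
Normalized counts plus 1 of 9 genes on logarithmic axes, 1 point per library, with the mean and SD of each group drawn beside the points (the lower bar ends at the level of a count of 0 where the SD exceeds the mean). Pf4, Clca3a1 and Apoe are lower in all 3 KO libraries than in all 4 WT libraries after 5-FU, and Gem and Emb in WT A2 lie above the other 3 WT libraries.

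Of the few genes that differed between untreated KO and WT HSCs, 2 act in mitosis, Cdc20 and Bub1. Cdc20 (ENSMUSG00000006398, chromosome 4, 118432901 to 118437352, GRCm38), the activator of the anaphase-promoting complex, rose 3.52-fold from 991 ± 203 to 3493 ± 473 (SD, n = 3 and 3; limma, Benjamini-Hochberg adjusted p = 0.0121). Bub1 (ENSMUSG00000027379, chromosome 2, 127801122 to 127831865), a spindle checkpoint kinase, rose 7.01-fold from 126 ± 145 to 882 ± 232 (limma adjusted p = 0.0385). Ribc1 (ENSMUSG00000025257, chromosome X, 152004582 to 152016295) rose from 0.352 ± 0.610, at the limit of detection, to 177 ± 87.9 (limma adjusted p = 0.0408). Nsun7 (ENSMUSG00000029206, chromosome 5, 66259897 to 66298026), a putative RNA methyltransferase, fell 44.3-fold from 163 ± 43.9 to 3.68 ± 6.38 (limma adjusted p = 0.0175). Bub1 rose 19.8-fold without WT D1, and Nsun7 was at 0 in KO D5 and D6. These 4 of 12846 genes were all that passed. In each of them the 3 KO libraries lay outside the range of the 3 WT libraries.

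Of the 47 mitosis and G2/M genes, 2 rose over all genes tested, Cdc20 and Bub1, and 29 when adjusted over the list alone, with a median log2 difference of 0.68 (camera adjusted p = 2.98e-26). The list call was lost with camera adjusted p = 0.156 with an estimated correlation between genes. Cdca8, a subunit of the chromosomal passenger complex, measured 1187 ± 216 in WT and 2519.8 ± 72.2 in KO and missed the threshold over all genes (limma adjusted p = 0.0644). None of the 51 DNA replication and G1/S genes passed, in full or over the list alone (median log2 0.24, camera adjusted p = 0.000263, adjusted p = 0.269 with an estimated correlation). Among them the exonuclease gene Exo1 measured 665 ± 292 and 1514 ± 144, cyclin E2 (Ccne2) 462 ± 208 and 963 ± 216, and the DNA ligase gene Lig1 815 ± 269.9 and 1805 ± 864 (limma adjusted p = 0.218, 0.288 and 0.291).

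None of the 25 ERK target and feedback genes passed over all genes in untreated cells, and 1 was lower when adjusted over the list alone (median log2 -0.01, a sign that flips under TMM scaling; camera adjusted p = 0.527). Spred1, an inhibitor of Ras-ERK signalling, measured 919.7 ± 78.6 in WT and 336 ± 83.5 in KO (limma adjusted p = 0.169). The immediate-early transcription factor gene Egr1 measured 824 ± 145 and 405 ± 218, and the EGF receptor ligand gene Hbegf 173 ± 147 and 37.2 ± 57.3 (limma adjusted p = 0.382 and 0.392). None of the 40 HSC identity genes passed over all genes and 1 over the list alone (camera adjusted p = 0.602). Hlf, an HSC transcription factor, was at 2987 ± 561 and 1669 ± 230.4, Zfp532 at 271 ± 84.2 and 31.7 ± 28.4, and Cldn12 at 163 ± 67.7 and 433 ± 166 (limma adjusted p = 0.321, 0.0971 and 0.412). Genes next in p that did not pass were Nfat5, the osmotic stress transcription factor (1133 ± 150.5 in WT, 212 ± 30.6 in KO, limma adjusted p = 0.0512), Edar (126 ± 21.8 and 6.68 ± 6.37, 0.0512), Fbp1 (2823 ± 902 and 554 ± 369, 0.0644). Also short of the threshold were Slc25a29, listed at 0 in all 3 WT libraries (98.8 ± 21.7 in KO, 0.0644), and Myo1e (194 ± 79.7 and 5.83 ± 10.1, 0.0836).

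Cdc20 missed the threshold without KO D6, Nsun7 without KO D5 or D6, Bub1 without KO D4, D5, D6 or WT D3, and Ribc1 without KO D4, KO D5, WT D1 or WT D3. Bub1 and Ribc1 also missed it with the alike 5-FU pair averaged or with the date term, Ribc1 with library weights or robust variances, Nsun7 and Ribc1 with a stricter filter, and Bub1 and Nsun7 on the log2 scale of normalized counts with a pseudocount of 0.5, 1 or 5. All 6 untreated libraries share an acquisition date, so the date term could not move the log2 differences of Bub1 and Ribc1 (median 1.41). Only their standard error could move, and it went from 0.227 to 0.234. At unadjusted p below 0.05 there were 1291 genes, and 1483 genes showed no overlap between the 2 groups, against 10% of genes by chance. The count of 4 became 25 without WT D2, 7 without WT D1, 1 without KO D5 or KO D6, 2 with the alike 5-FU pair averaged or with acquisition date as a term, and 0 with limma-voom on the recovered reads or with only the 6 untreated libraries in the fit. Camera called 13 of 35 lists with a preset correlation and 0 with an estimated one, and fry, a rotation test of whether a list's genes move on balance one way, called 3.

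After 5-FU, KO HSCs held fewer megakaryocytic and erythroid transcripts than WT HSCs and more transcripts of DNA replication, nucleotide synthesis and ribosome assembly. Pf4 (ENSMUSG00000029373, chromosome 5, 90772435 to 90773383, GRCm38), a platelet chemokine, fell 9.19-fold, from 26736 ± 7494 in WT to 2910.4 ± 1562 in KO (SD, n = 4 and 3; limma, Benjamini-Hochberg adjusted p = 3.23e-05). Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), encoding apolipoprotein E, fell 7.71-fold, from 54184 ± 5067 to 7024 ± 1137 (limma adjusted p = 5.99e-09). Clca3a1 (ENSMUSG00000056025, chromosome 3, 144729677 to 144760977), of the calcium-activated chloride channel regulator family, fell 26.97-fold, from 5576 ± 1054 to 207 ± 132 (limma adjusted p = 6.27e-08). Emb (ENSMUSG00000021728, chromosome 13, 117208536 to 117274415), encoding the transporter chaperone embigin, rose 14.2-fold, from 268 ± 395 to 3793 ± 1485 (limma adjusted p = 4.29e-05), and without WT A2 it rose 53.9-fold.

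In all, 1395 of 12846 genes differed, 689 higher and 706 lower in KO. Of these, 402 differed at least 2-fold on the deposited variance-stabilized scale, which understates the change of low genes. The higher genes with the largest log2 change also held Gem (ENSMUSG00000028214, chromosome 4, 11704457 to 11714752), a small GTPase, at 526 ± 993 in WT and 6631 ± 2470.5 in KO, and Lcp1, an actin-bundling protein, at 1258 ± 725 and 6319 ± 510.3 (limma adjusted p = 0.000532 and 4.19e-05). Gch1, of tetrahydrobiopterin synthesis, rose 5.13-fold and the mitotic kinase gene Nek6 17.01-fold, and the gluconeogenic enzyme gene Fbp1 rose 9.66-fold. Gem, Emb, Nek6 and Fbp1 were above the other WT libraries in WT A2, at 2013, 859.8, 103 and 206, and without A2 the WT means of Gem, Nek6 and Fbp1 were 29.8, 0.704 and 2.53. Among the lower genes, Fcer1a, the alpha chain of the IgE receptor, fell 43.6-fold (29.04-fold without KO A6, and to 0.650 without A5), Ypel3 14.2-fold, Mfsd2b, a sphingolipid exporter of red cells and platelets, 13.2-fold, and Plac8 9.24-fold. No overlap between the KO and the WT libraries was seen in 3466 of the 12846 genes tested, and 1363 of them were among the 1395. Chance gives 5.71% of genes if all libraries are independent, and 10%, as for 3 against 3 libraries, if A3 and D4 are 1 sample.

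Of 23 megakaryocyte and platelet genes, 19 fell and 0 rose (20 fell when adjusted over the list alone), with a median log2 difference of -1.36 (camera adjusted p = 2.32e-18, and adjusted p = 0.00665 with an estimated correlation). Gp1bb, a subunit of the platelet receptor for von Willebrand factor, fell 11.4-fold from 2172 ± 323 to 190.3 ± 56.4, and Treml1, a platelet granule receptor, fell 13.4-fold from 3270.5 ± 1202 to 244 ± 63.8 (limma adjusted p = 1.04e-05 and 2.89e-05). Of 19 erythroid genes, 9 fell (10 over the list alone), with a median of -0.48 (camera adjusted p = 1.82e-06, and adjusted p = 0.00665 with an estimated correlation). Rhag, of the red cell Rh complex, fell 23.97-fold from 1439 ± 449 to 60.01 ± 50.3, the water channel gene Aqp1 fell 6.74-fold and the biliverdin reductase gene Blvrb 2.41-fold. Of 12 neutrophil genes, 4 fell (6 over the list alone; camera adjusted p = 6.44e-05, and adjusted p = 0.0139 with an estimated correlation). S100a8, a calprotectin subunit, fell 26.3-fold from 514 ± 264 to 19.6 ± 10.2, the granule protease gene Prtn3 fell 1.78-fold, and Lcn2, at 57.5 ± 24.8 in WT, was at 0 in all 3 KO libraries (limma adjusted p = 0.000512, 0.00203 and 0.00380).

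Of 51 DNA replication and G1/S genes, 28 rose and 0 fell (34 rose over the list alone), with a median log2 difference of 0.74 (camera adjusted p = 5.4e-18, and adjusted p = 0.0180 with an estimated correlation). Hells, a chromatin remodeller, rose 3.85-fold from 644 ± 179 to 2481 ± 33.5, and cyclin E2 (Ccne2) rose 4.11-fold from 485 ± 142 to 1993 ± 282 (limma adjusted p = 4.81e-05 and 0.000279). Of 20 fluorouracil and pyrimidine metabolism genes, 11 rose (13 over the list alone; median 0.86, camera adjusted p = 3.36e-07, and adjusted p = 0.0180 with an estimated correlation). Dut, which hydrolyses dUTP, rose 2.22-fold from 5275 ± 1598 to 11726 ± 1435, the nucleoside diphosphate kinase gene Nme1 2.51-fold and Rrm1, the large subunit of ribonucleotide reductase, 1.95-fold. Of 42 DNA repair genes, 5 rose (8 over the list alone; camera adjusted p = 0.000153, and adjusted p = 0.0134 with an estimated correlation), among them Topbp1 (2.11-fold), the helicase gene Brip1 (3.92-fold) and the mismatch repair gene Msh6 (1.78-fold).

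Of 43 ribosome biogenesis genes, 16 rose and 0 fell (25 rose over the list alone; median log2 0.53, camera adjusted p = 4.96e-13, and adjusted p = 0.0134 with an estimated correlation). The ribosome assembly factor gene Mrto4 rose 5.26-fold from 390.3 ± 109.8 to 2053 ± 77.2, nucleolin (Ncl) 2.05-fold and nucleophosmin (Npm1) 1.90-fold. In the ATF4 amino acid response list of 26 genes, 13 rose and 2 fell (15 and 2 over the list alone; camera adjusted p = 1.51e-06, and adjusted p = 0.0180 with an estimated correlation). Phgdh (ENSMUSG00000053398, chromosome 3, 98313170 to 98339990), of serine synthesis, rose 3.21-fold from 3406 ± 884 to 10919.9 ± 1438 and the tryptophanyl-tRNA synthetase gene Wars 3.95-fold (limma adjusted p = 6.44e-05 and 0.000757). Ddit3, the stress transcription factor CHOP, fell 5.72-fold from 991 ± 239 to 173 ± 75.1 (limma adjusted p = 0.000220). Of 75 nuclear genes of oxidative phosphorylation, 32 rose and 0 fell (43 over the list alone), such as cytochrome c (Cycs, 2.50-fold), Cyc1 (1.78-fold) and the ATP synthase subunit gene Atp5o (1.62-fold). The call of that list (camera adjusted p = 3.82e-15) was lost, at adjusted p = 0.154 with an estimated correlation.

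Of 60 interferon response genes, 14 fell and 0 rose (18 fell over the list alone; median log2 -0.42, camera adjusted p = 7.16e-08, and adjusted p = 0.0276 with an estimated correlation). The class I histocompatibility genes H2-T23 and H2-K1 fell 2.63-fold and 1.71-fold, from 10384 ± 1150.4 to 3948 ± 619.8 and from 36277 ± 2931 to 21179 ± 1875, and the antiviral gene Oasl2 fell 2.74-fold (limma adjusted p = 4.94e-05, 0.000371 and 0.00154). Of 40 HSC identity genes, 12 fell and 1 rose (15 and 3 over the list alone), among them Pdzk1ip1 (4.15-fold lower) and the G protein subunit gene Gng11 (2.90-fold). The call (camera adjusted p = 0.000421) was lost, at adjusted p = 0.0674 with an estimated correlation. Of 25 ERK target and feedback genes, 5 rose and 2 fell, in full and over the list alone, and the list was not called (camera adjusted p = 0.0894). Cyclin D1 (Ccnd1), which drives entry into S phase, rose 4.09-fold from 324 ± 114 to 1325 ± 11.5 (limma adjusted p = 0.000941). The ETS factor gene Etv4 was at 0 in all 4 WT libraries and at 61.1 ± 12.9 in KO, and Ier3, an immediate-early gene, fell 4.58-fold from 1414 ± 311 to 309 ± 95.6 (limma adjusted p = 0.00109 and 0.000302). Of 31 p53 target genes, 3 rose and 1 fell, and the list was not called (camera adjusted p = 0.187).

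The count of 1395 fell to 913 with the alike WT pair averaged (900 of the genes kept), to 876 and 890 without D4 or A3, to 756, 694 and 793 without KO A5, A6 or A8, and to 881 with acquisition date as a term, and rose to 5611 with library weights. With limma-voom 601 genes were higher and 360 lower, and under TMM scaling 786 and 596. Leaving out D4 is also the comparison within 1 acquisition date. Of the named genes, Brip1 and Msh6 missed the threshold with the pair averaged or with the date term. In the 4 named genes that the date term lost, the median size of the log2 difference went from 0.90 to 0.77 and its standard error from 0.241 to 0.253. Brip1 also missed it without A5, A6, A8, A3 or D4, Msh6 without A5, A6, A4 or D4 or with quantile normalization, Topbp1 without A5, A6 or D4 or with the date term, and Nek6 with limma-voom. With a preset correlation camera called 19 lists, and fry called 23.

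**Figure D3:**
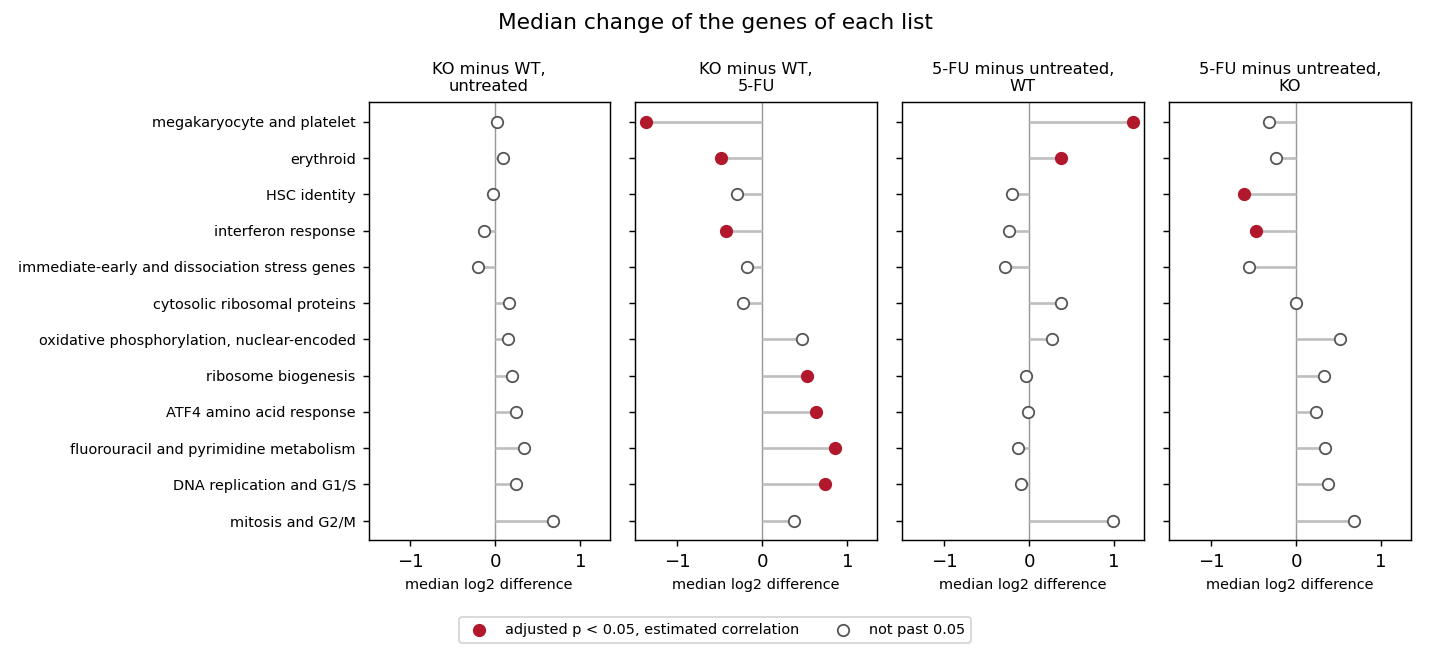
Median log2 difference of 12 gene lists in the 4 pairwise comparisons, 1 point per list, filled where the adjusted p passes 0.05 with an estimated correlation between genes. The megakaryocyte and platelet list lies at 1.22 after 5-FU in WT and at -1.36 between KO and WT after 5-FU.

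In WT HSCs, 5-FU was followed by higher megakaryocytic and erythroid transcripts and lower transcripts of Fos and of class II histocompatibility genes. Pf4 rose 22.5-fold, from 1189 ± 402 to 26736 ± 7494 (SD, n = 3 and 4; limma, Benjamini-Hochberg adjusted p = 5.1e-06). F2rl2, a thrombin receptor, rose 63.3-fold from 52.7 ± 54.02 to 3339 ± 623 and the adhesion molecule gene Selp, P-selectin, 16.3-fold from 194 ± 33.3 to 3163 ± 786 (limma adjusted p = 1.11e-06 and 5.93e-06). Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273, GRCm38), an immediate-early transcription factor, fell 71.5-fold from 2547 ± 1283 to 35.6 ± 27.1, and H2-Aa, a class II histocompatibility chain, fell from 2137 ± 336 to 85.5 ± 96.7 (limma adjusted p = 3.01e-05 and 8.49e-05). F2rl2 rose 145-fold without untreated WT D2, and the mean of H2-Aa after 5-FU was 38.8 without A2.

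In all, 858 genes changed, 478 up and 380 down. Clca3a1 rose 9.25-fold, Mfsd2b 11.1-fold, the chemokine-binding receptor gene Ackr1 14.9-fold, the histone gene Hist2h3b 19.97-fold and the carboxylesterase gene Ces2g 7.83-fold. Emb fell 27.4-fold, Fbp1 52.9-fold, the sulfotransferase gene Sult1a1 45.5-fold, the invariant chain gene Cd74 8.85-fold, the interferon-induced GTPase gene Tgtp1 6.47-fold and Serpinf1 13.9-fold. Without A2, Emb fell 104-fold and the mean of Fbp1 after 5-FU was 2.53, and without untreated WT D3, Sult1a1 fell 27.2-fold. The 5-FU and untreated libraries did not overlap in 2149 of the 12846 genes tested, and 816 of them were among the 858. By chance 5.71% of genes would not overlap if all libraries are independent, and 10% if A3 and D4 are 1 sample. In lists drawn up after the data were seen, 6 of 10 class II histocompatibility genes fell (camera adjusted p = 0.00850 with an estimated correlation) and 16 of 57 histone genes of the Hist clusters rose (0.00850 likewise).

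Of 47 mitosis and G2/M genes, 28 rose and 0 fell (39 rose over the list alone; median log2 0.99, camera adjusted p = 1.16e-26), although adjusted p = 0.0724 with an estimated correlation. The centromere kinesin gene Cenpe rose 7.44-fold from 423 ± 259 to 3148 ± 593, Cdc20 4.31-fold and Cdca8 2.85-fold (limma adjusted p = 2.74e-05, 3.05e-05 and 0.000113). Of 23 megakaryocyte and platelet genes, 16 rose and 1 fell (18 and 2 over the list alone; median 1.22, camera adjusted p = 2.77e-17, and adjusted p = 0.0172 with an estimated correlation), with Gp1bb 6.28-fold higher. Of 19 erythroid genes, 4 rose and 1 fell (5 and 1 over the list alone; camera adjusted p = 0.000539, and adjusted p = 0.0351 with an estimated correlation). Rhag rose 15.9-fold from 90.5 ± 104 to 1439 ± 449, and the erythroid transcription factor genes Gata1 and Klf1 rose 4.69-fold and 9.85-fold. Without untreated WT D1, Cenpe rose 11.5-fold and Klf1 21.5-fold, and without untreated WT D2, Rhag rose 44.7-fold and Gata1 7.22-fold. Of 79 cytosolic ribosomal protein genes, 30 rose and 1 fell (42 and 2 over the list alone; camera adjusted p = 2.54e-13, but adjusted p = 0.305 with an estimated correlation), such as Rpl39 (3.22-fold), Rps29 (3.41-fold) and Rps28 (2.78-fold). Ribosomal protein genes held 9.25% of the reads in A3 and 11.05% in its near copy D4, sequenced on the other flowcell. In untreated WT they held 8.09% to 9.36%. With the date term the log2 change of Rps29 went from 1.66 to 2.28. An effect of the sequencing run on these genes was not tested and cannot be told apart here.

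Of 60 interferon response genes, 9 fell and 3 rose (12 and 3 over the list alone; camera adjusted p = 0.00141, but adjusted p = 0.234 with an estimated correlation). Ifitm1, an interferon-induced membrane protein, fell 3.06-fold from 14841 ± 1989.5 to 4857 ± 456, and the immunity-related GTPase genes Irgm1 and Iigp1 fell 1.78-fold and 3.98-fold. Of 19 immediate-early and dissociation stress genes, 5 fell (8 over the list alone; camera adjusted p = 0.00175, but adjusted p = 0.199 with an estimated correlation), with Ier2 2.86-fold and the MAP kinase phosphatase gene Dusp1 3.77-fold lower. Of 40 HSC identity genes, 7 fell and 4 rose (11 and 5 over the list alone; camera adjusted p = 0.0108, but adjusted p = 0.234 with an estimated correlation). Procr, the endothelial protein C receptor used to sort HSCs, fell 16.1-fold from 880.0 ± 95.2 to 54.7 ± 74.2, and Hlf 4.86-fold from 2987 ± 561 to 614 ± 294 (limma adjusted p = 0.000113 and 0.000115). Without A4, Procr fell 48.6-fold. Of 25 ERK target and feedback genes, 3 fell, Fos, Ier2 and Egr1 (Egr1 3.63-fold), and 6 over the list alone, with the list not called (camera adjusted p = 0.0614).

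Iigp1 missed the threshold without untreated WT D3. With the date term, Iigp1, Irgm1, Dusp1, Egr1 and Gata1 missed it, as their median log2 change went from 1.47 to 1.24 in size and its standard error from 0.255 to 0.400. The count of 858 became 510 with the alike pair averaged (505 of the genes kept), 464 and 532 without D4 or A3, 1732 with library weights, 415 with only the WT libraries in the fit and 219 with acquisition date as a term. The date of the cells and the treatment cannot be told apart except through D4, and D4 is nearly a copy of A3, so that term rests on 1 library.

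In KO HSCs, 5-FU was followed by lower HSC identity and interferon transcripts and higher transcripts of Gem, Cd53 and Id1. Gem rose 62.4-fold, from 106 ± 31.7 to 6631 ± 2470.5 (SD, n = 3 and 3; limma, Benjamini-Hochberg adjusted p = 0.00156). Cd53, a leukocyte tetraspanin, rose 24.7-fold from 31.3 ± 50.8 to 774 ± 159 and Id1, an inhibitor of helix-loop-helix factors, 10.4-fold from 116 ± 103 to 1207 ± 160.0 (limma adjusted p = 0.00437 and 0.00133). Aldoc, a glycolytic aldolase, fell 76.2-fold from 936 ± 335 to 12.3 ± 18.98, and Txnip, a thioredoxin-binding protein high in quiescent HSCs, fell 3.64-fold from 9539 ± 739.9 to 2621 ± 161 (limma adjusted p = 0.000253 and 2.12e-06). Without untreated KO D5 the untreated mean of Cd53 was 1.98, without untreated KO D4 Id1 rose 16.0-fold, and without A6 the mean of Aldoc after 5-FU was 1.32.

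In all, 761 genes changed, 357 up and 404 down. The beta-globin gene Hbb-bt rose 5.53-fold, the linker histone gene Hist1h1b 4.28-fold and Emilin2 17.4-fold. Sult1a1 fell 25.4-fold, Trim47 12.3-fold, Art4 9.91-fold, H2-Aa 7.25-fold, Fos 11.7-fold and the glucocorticoid-induced gene Tsc22d3 4.80-fold. Without untreated KO D5 the untreated mean of Emilin2 was 1.59, without A8 H2-Aa fell 12.1-fold, and without A5 Fos fell 18.6-fold. The 5-FU and untreated libraries did not overlap in 3704 of the 12846 genes tested, against 10% of genes by chance, and 758 of them were among the 761. Of the 10 class II genes, 7 fell (camera adjusted p = 0.00220 with an estimated correlation), and of the 57 histone genes 5 rose (0.137 likewise), again in lists drawn up after the data were seen.

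Of 40 HSC identity genes, 11 fell and 0 rose (20 fell over the list alone; median log2 -0.61, camera adjusted p = 3.21e-11, and adjusted p = 0.0184 with an estimated correlation). Pdzk1ip1 fell 4.19-fold from 3772 ± 458 to 899.7 ± 258 and Gng11 3.31-fold. Of 60 interferon response genes, 17 fell and 1 rose (27 and 1 over the list alone; median -0.48, camera adjusted p = 5.78e-12, and adjusted p = 0.0312 with an estimated correlation), with Ifitm1 4.99-fold, H2-T23 2.65-fold and H2-K1 2.02-fold lower. Of 27 HSC quiescence and dormancy genes, 5 fell and 1 rose (7 and 1 over the list alone; camera adjusted p = 0.00274, but adjusted p = 0.0858 with an estimated correlation). They included Ndn (3.21-fold lower, 1774 ± 370.4 to 553 ± 91.7). Of 7 genes used to sort HSCs, 3 fell and 1 rose (5 and 1 over the list alone; camera adjusted p = 0.00288, but adjusted p = 0.0839 with an estimated correlation). Kit, the stem cell factor receptor, fell 2.90-fold from 4460.0 ± 548 to 1535 ± 94.3, Ly6a, encoding Sca-1, fell 2.32-fold, and Cd48, absent from the surface of most HSCs, rose 9.13-fold from 143 ± 123 to 1303 ± 492 (limma adjusted p = 0.00195, 0.00887 and 0.0140).

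Of 75 nuclear genes of oxidative phosphorylation, 31 rose and 0 fell (53 over the list alone; median log2 0.51, camera adjusted p = 3.83e-24, but adjusted p = 0.0858 with an estimated correlation), such as Cox7c (3.00-fold), Ndufa4 (2.08-fold) and Cox5a (2.07-fold). Of 47 mitosis and G2/M genes, 14 rose (24 over the list alone; camera adjusted p = 5.15e-16, but adjusted p = 0.0858 with an estimated correlation), with Kif20b 2.85-fold, Cks2 2.42-fold and survivin (Birc5) 2.31-fold higher. Of 19 immediate-early and dissociation stress genes, 6 fell (7 over the list alone; camera adjusted p = 1.34e-05, but adjusted p = 0.0839 with an estimated correlation), among them the NF-kB inhibitor gene Nfkbia (2.72-fold), the mRNA decay factor gene Zfp36 (4.20-fold) and Dusp1 (3.98-fold). Of 25 ERK target and feedback genes, 3 rose and 3 fell (4 and 4 over the list alone; camera adjusted p = 0.984), with Ier3 3.67-fold lower and Etv4 at 0 in all 3 untreated libraries and at 61.1 ± 12.9 after 5-FU. The megakaryocyte and platelet list had a median of -0.31, with 1 gene lower and 0 higher, and was not called (camera adjusted p = 0.188).

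The count of 761 became 356 without KO A5 or A6, 468 without A8, 444 and 449 without untreated KO D4 or D6, 1466 with library weights and 448 with limma-voom. With acquisition date as a term it became 7, and of the named genes Txnip alone passed. In the other 33 the median size of the log2 change was 1.55 against 1.49 before and its standard error rose from 0.224 to 0.401, while Gem went from 4.04 to 2.53. The date term is set only by the difference of WT D4 from WT A2, A3 and A4 after 5-FU. Gem was at 2013 in A2 against 0 to 83.7 in the other WT libraries after 5-FU. Its shift therefore cannot be read as an effect of date. Cd48 missed the threshold without A5, A8 or untreated KO D4, Gem and Cd48 on the log2 scale with a pseudocount of 0.5 or 1 (Cd48 also with 5), and Art4, Cd48, Cd53, Emilin2, Fos and Sult1a1 with limma-voom. Under TMM scaling 464 genes were higher and 340 lower.

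The response to 5-FU itself differed between the genotypes in 365 genes, 134 with a higher and 231 with a lower response in KO (limma interaction, Benjamini-Hochberg adjusted). For Pf4 the KO response minus the WT response was -3.07 on the log2 scale (SE 0.49, limma adjusted p = 0.00505), for Clca3a1 -3.72 (SE 0.32, adjusted p = 1.01e-05), for F2rl2 -3.15 and for Mfsd2b -2.97 (both adjusted p = 0.000286). The response in KO was higher for Gem by 4.25 (SE 0.87, limma adjusted p = 0.0156), Emb by 3.63 (0.00166), Fbp1 by 3.49 (0.00120) and Lcp1 by 2.19 (0.00505). Hsdl1 (2.27, limma adjusted p = 0.0490) and Xlr3b (-2.97, adjusted p = 0.0307) also passed, with Hsdl1 near 0 in A3 and D4 (1.45 and 1.99) against 268 and 518 in A2 and A4.

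Of the 231 genes with a lower response in KO, 114 rose in WT and were not called in KO, 83 fell in KO and were not called in WT, and 10 rose in WT and fell in KO. Of the 134 with a higher response, 67 rose in KO and were not called in WT, 41 fell in WT and were not called in KO, and 6 fell in WT and rose in KO. Of 23 megakaryocyte and platelet genes, 15 had a lower response (19 over the list alone; median log2 -1.47, camera adjusted p = 7.81e-18, and adjusted p = 0.0133 with an estimated correlation). Among them were Gp1bb at -2.39 and Plek, a platelet protein kinase C substrate, at -2.53 (limma adjusted p = 0.00120 and 0.00166). Of 19 erythroid genes, 3 had a lower response (8, and 1 higher, over the list alone; camera adjusted p = 2.69e-05, and adjusted p = 0.0133 with an estimated correlation). They were Rhag at -2.86, Aqp1 at -1.94 and Klf1 at -2.25 (limma adjusted p = 0.00247, 0.0127 and 0.0256). Of 79 cytosolic ribosomal protein genes, 10 had a lower and 1 a higher response (27 and 3 over the list alone; camera adjusted p = 1.46e-07, but adjusted p = 0.406 with an estimated correlation), such as Rps28 (-1.25) and Rpl37a (-1.16). The unlike share of ribosomal protein reads in A3 and D4, given above, limits this result too. Of 51 DNA replication and G1/S genes, 3 had a higher response, Tipin (1.03), Dut (1.03) and Hells (1.01), and 4 over the list alone (camera adjusted p = 2.56e-07, but adjusted p = 0.187 with an estimated correlation).

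The 365 became 237 with the alike pair averaged (229 of the genes kept), 198 and 227 without D4 or A3, 178 and 140 without KO A5 or A6, 212 and 225 without untreated KO D4 or D6, 199 with the date term and 864 with library weights. With limma-voom 338 genes passed, 168 higher and 170 lower. With the alike pair averaged, Hsdl1, Klf1, Dut and Hells missed the threshold. Dut, Hells and Hsdl1 each missed it without 11 of the 13 libraries in turn, Dut being called without A2 or untreated WT D3, Hells without A2 or untreated WT D1, and Hsdl1 without A2 or A4. Tipin was called only without A2, untreated KO D5, untreated WT D2 or untreated WT D3. Xlr3b missed the threshold without A4, A5, A6, untreated KO D4, untreated KO D6, untreated WT D1 or untreated WT D3, Klf1 without A3, D4, A5, A6 or untreated KO D4, and Gem without A6 or with pseudocounts of 0.5, 1 and 5. Other settings that ended a call were the date term (Dut, Hells, Hsdl1, Klf1 and Tipin, whose median size of 1.03 became 1.05 and standard error went from 0.260 to 0.274), limma-voom (Aqp1, Hells, Klf1, Xlr3b), library weights (Rpl37a), TMM scaling (Hsdl1), quantile normalization (Dut, Hells, Tipin) and pseudocounts of 0.5 or 1 (Xlr3b) and of 0.5, 1 or 5 (Dut, Hells, Hsdl1, Klf1).

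**Figure D4:**
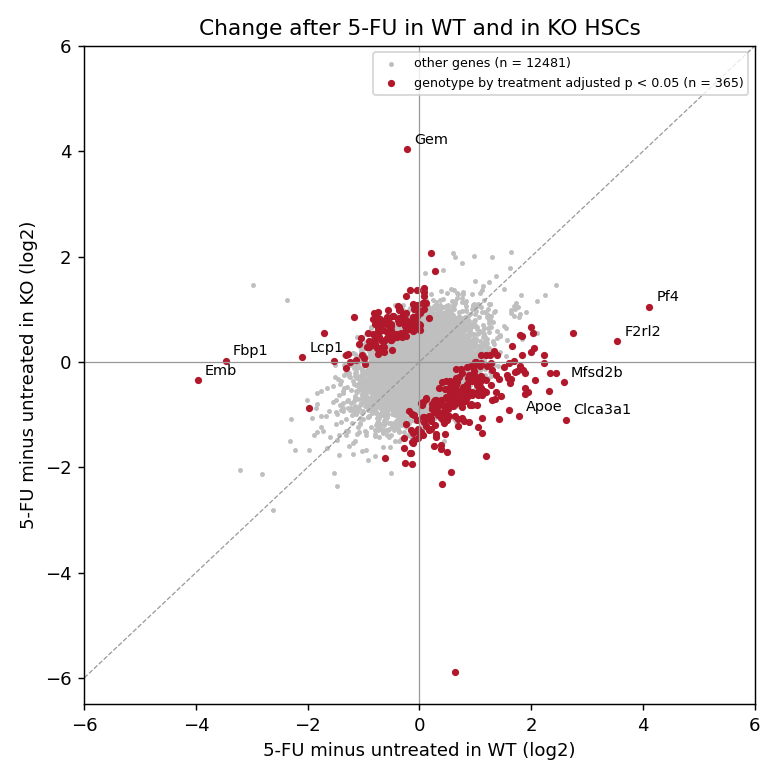
Log2 change after 5-FU in WT (horizontal) and in KO (vertical) for 12846 genes, with the 365 genes of the genotype by treatment interaction in red and equal change on the dashed line. Pf4 lies at 4.11 in WT and Gem at 4.04 in KO.

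Across genes, which are not independent replicates, the 5-FU change in WT and in KO had a Pearson correlation of 0.239 and a Spearman correlation of 0.193. The 2 comparisons share no libraries. Both called 74 genes higher, against 13.3 for independent lists, and 90 lower, against 12.0, and 16 genes went opposite ways, 10 up in WT and down in KO and 6 the reverse. Fos, Sult1a1, H2-Aa and Ifitm1 fell in both genotypes. The acquisition date also changed with treatment in both genotypes, except for WT D4. In these shared calls an effect of date therefore cannot be told apart from an effect of 5-FU. The KO effect in untreated cells and that after 5-FU correlated at 0.0909 (Spearman 0.1003), and none of the 4 genes called in untreated cells was called after 5-FU. Genes of near-identical families named above, among them the histone, ribosomal protein, class I and class II histocompatibility, globin, Xlr3 and Clca3a genes, are uncertain where the counting could split reads between copies.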

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

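The tests of A3 and D4, of a KO library or KO cells or RNA in A2, of the megakaryocyte rise and of alleles near Map2k1 were chosen after the result was seen. The counts over other splits of the libraries and the test of a weaker 5-FU response in A2 were planned before.

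Within the 4 WT libraries after 5-FU, 14 of 121 measures had a library further from the others than Dixon's 95% limit, and chance gives such a gap in about 1 in 20 groups of 4 independent libraries. A3 and D4, nearly alike, make a gap for A2 or A4 more frequent than that. WT A2 was high for Fbp1 (206 against 1.33 to 4.35 in the other 3), Gem (2013 against 0 to 83.7), Emb (860 against 54.5 to 82.7), Mrto4 (554 against 327 to 351), Nek6 (103 against 0 to 1.45), Spred1 (768 against 317 to 377) and Ier3 (1878 against 1212 to 1282). WT A4 was high for Hlf (1052 against 416 to 496), Topbp1 (1158 against 577 to 646), Procr (165 against 1.16 to 28.6) and Ndn (938 against 336 to 435), and low for Cd53 (305 against 478 to 501) and Tipin (4257 against 4863 to 4931). WT D4 was high for Cks2 (3906 against 2349 to 2570). The groups of 3 were not tested for such gaps.

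The response to 5-FU differed between WT and KO by the interaction test in 365 genes, 52 of them among the 116 genes named in the text. The KO response minus the WT response, on the log2 scale, was Clca3a1 -3.72, F2rl2 -3.15, Pf4 -3.07, Mfsd2b -2.97, Xlr3b -2.97, Rhag -2.86, Apoe -2.81, Ackr1 -2.65, Ces2g -2.54, Plek -2.53, Treml1 -2.50, Gp1bb -2.39, Klf1 -2.25, Ypel3 -2.21, Selp -2.19, Fcer1a -2.10, S100a8 -2.05, Aqp1 -1.94, Tsc22d3 -1.79, Trim47 -1.65, Pdzk1ip1 -1.56, Txnip -1.56, Ddit3 -1.48, Nfkbia -1.45, Ribc1 -1.35, Rps29 -1.34, Ier3 -1.33, H2-T23 -1.32, Rps28 -1.25, Rpl37a -1.16, Gng11 -1.16, H2-K1 -0.90 for the genes with a lower response in KO. For those with a higher response it was Gem 4.25, Emb 3.63, Fbp1 3.49, Hsdl1 2.27, Lcp1 2.19, Id1 1.87, Spred1 1.49, Nfat5 1.44, Mrto4 1.33, Phgdh 1.24, Nsun7 1.16, Cycs 1.06, Nme1 1.03, Tipin 1.03, Dut 1.03, Hells 1.01, Edar 0.94, Npm1 0.91, Etv4 0.69, Ncl 0.68. Of 100 draws of the genotype labels within each treatment, the real one included, 4 called as many genes, and the highest other draw called 566. The 3 other draws, with 474, 519 and 566 genes, kept the real 5-FU groups and exchanged labels among the untreated libraries only. The draws therefore restate the difference of the 5-FU groups, and they do not exclude chance for an interaction.

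For KO against WT after 5-FU, 1 of 35 splits called as many genes, the real one with 1395, against 815 for the highest other, A3, A4 and D4 against A2 and the 3 KO libraries. For 5-FU against untreated in WT, 1 of 35 splits called as many, the real one with 858, against 309. Both sets of splits take A3 and D4 as separate, and with that pair as 1 replicate there are 10 splits, too few for a share under 0.05. Chance is thus excluded at 0.05 only if all these libraries are independent, A3 and D4 included. Pairs of the 3 KO libraries after 5-FU correlated at 0.966 to 0.977, against 0.912 to 0.943 for same-group pairs other than A3 and D4. Independence of these KO libraries is not shown either, since separate animals are not stated. For KO against WT in untreated cells 3 of 10 splits called as many (4 genes, highest other 4), and for 5-FU against untreated in KO 1 of 10 (761 genes, highest other 0), again with too few splits.

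WT A3 and D4 after 5-FU were nearly alike. Of the 122 genes with at least 10 reads in A3 and none in A2 and A4, 100% had at least 10 reads in D4, and 85.9% of 142 such genes of D4 had them in A3, against 47.7% and 44.7% for A2 and A4 among genes absent from A3 and D4. The median chi-square of low genes between A3 and D4 was 1.69, against 6.48 for the lowest other pair of a group, which argues against 2 separate animals with merely similar cells. One cDNA sequenced in 2 runs is a candidate explanation, and the labels give these libraries different acquisition years and sample numbers. A pool of cells taken from 1 animal was not tested and stays open.

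WT A2 lay between the other 5-FU WT libraries and the 5-FU KO libraries. Each position was measured over genes called without the libraries it concerns. A2 had gone a median of 0.355 of the way to KO over 542 genes, A4 0.0373 over 419 genes, and A3 and D4 0.0374 over 330 genes. A KO library under the label A2 would lie near 1, and the upper quartiles of 0.484 over the 217 genes higher in KO and 0.650 over the 325 lower ones argue against it. Cells or RNA of KO in A2 would bring all transcripts of KO in a like share, near the 0.246 of the higher genes. Of 23 genes with at least 50 in each KO library and at most 5 in A3, A4 and D4, 10 lay in A2 below 0.0614 of the KO mean (5 of them at 0) and 5 lay above the KO mean. With a median of 0.230 and quartiles of 0.0120 and 0.761, this argues against such a mix as the whole cause. A weaker response to 5-FU might move A2 back toward untreated WT, and its median fraction of that way was 0.133, against 0.157 for A4 and 0.00116 for A3 and D4. A weaker response cannot be told apart from a true difference of these cells, which was not tested, and without A2 the KO against WT count after 5-FU was 1569.

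The megakaryocyte and platelet list was called higher after 5-FU in WT and was not called in KO. Platelet RNA from other cells would bring Ppbp and Tubb1, abundant in platelets, and these together gained 0.560% as much as Pf4. The acquisition date, shared by both genotypes after 5-FU except for WT D4, would move both, and the median log2 change of the list was -0.31 in KO and 1.22 in WT. Committed progenitors in the sort gate and a changed state of HSCs were not tested and both stay open. A response of WT HSCs that MEK1 loss prevents is a hypothesis from these data and was not tested.

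Alleles linked to Map2k1 were tested as a source of the KO against WT calls after 5-FU. The test weighs the share of genes called and does not exclude such alleles for single genes. Myo1e, on the same chromosome (9, start 70207350), measured 194 ± 79.7 in untreated WT and 5.83 ± 10.1 in untreated KO. It did not pass there (limma adjusted p = 0.0836). Of 146 tested genes within 10 Mb of Map2k1, 15 were called (10.3%), against 10.9% of the rest (Fisher exact test, p = 1). Calls were thus no more frequent near Map2k1 than elsewhere. The window holds only 146 of the 12846 genes tested, and effects of a linked allele on genes elsewhere would not show in it. The test therefore cannot decide whether such alleles are a main source of the calls.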

How the results depend on the processing

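All settings below were planned before the data were examined except limma-voom, the pseudocount of 1, the averaging of A3 and D4, and the left-out libraries for Map2k1, which were chosen after seeing the data. In the order KO against WT untreated, KO against WT after 5-FU, 5-FU in WT, 5-FU in KO and interaction, the counts were 4, 1395, 858, 761 and 365. With an adjusted p under 0.1 they were 17, 2066, 1473, 1281 and 676. With at least a 2-fold change on the variance-stabilized scale, 402 genes remained in KO against WT after 5-FU. For 5-FU in WT and in KO, 357 and 290 remained. With library weights (arrayWeights), 3, 5611, 1732, 1466 and 864 passed. With acquisition date as a term, 2, 881, 219, 7 and 199 passed. With limma-voom 0, 961 (601 higher, 360 lower), 1021, 448 (270 and 178) and 338 (168 and 170) passed. With A3 and D4 averaged, 2, 913, 510, 698 and 237 passed. With only the groups of the comparison, 0, 1846, 415 and 1029 passed, and for the interaction those groups are all libraries, so there is no separate value. In untreated cells a pseudocount of 0.5 gave 11, a pseudocount of 1 gave 9, and a stricter filter gave 2. TMM scaling changed the split of 5-FU in KO from 357 higher and 404 lower to 464 and 340. With 1 library left out in turn the counts ranged over 1 to 25, 694 to 1569, 464 to 990, 356 to 630 and 140 to 476. The lowest were without KO D5 or D6, A6, D4, A5 or A6, and A6, and the highest without WT D2, A2, A2, untreated KO D5 and A2. Camera called 13, 19, 11, 16 and 13 lists with a preset correlation and 0, 9, 2, 2 and 2 with an estimated one, and fry called 3 in untreated cells. All these list counts take A3 and D4 as 2 replicates, and an estimated correlation was not combined with the averaged pair. Of 139 called results for named genes, 83 were called in every alternative and left-out set run for their comparison, and 0 of the 139 changed direction in any. Of the other 29 named results, which were not called, 9 changed sign in at least 1. With single libraries left out or the pair averaged, the Map2k1 log2 difference ranged over -0.47 to -0.85 in untreated cells and -0.78 to -1.15 after 5-FU, and it reached -0.95 and -1.45 with a pseudocount of 0.5. No paired analysis was possible because only the number D4 occurs in 2 groups, untreated KO and 5-FU WT. The planned edgeR and DESeq2 fits were left out, although both tools were at hand, and limma-voom on the recovered reads took their place. Why the library weights move the counts so far was not tested, and the date term, which widens the standard errors of the 5-FU changes, leans on WT D4 alone, a near copy of A3.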

Other observations

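All tests in this part were chosen after the result was seen.

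Gm29216, an unprocessed pseudogene, measured 20.05 to 139 in the 3 KO libraries after 5-FU and 12181 to 50296 in the other 10 libraries (log2 -6.84, limma adjusted p = 3.17e-11 against 5-FU WT). mt-Co1 measured 265481 in KO and 335378 in WT after 5-FU (log2 -0.34, limma adjusted p = 0.0211). Of the 443 windows of 50 bases in the Gm29216 transcript, 430 occur unchanged in mt-Co1, so reads of one copy can be counted for the other and both values are uncertain. The other 10 libraries include untreated KO, so the loss of Gm29216 marks the KO group after 5-FU and not the genotype alone. Since mt-Co1 was also lower in that group, a move of reads from Gm29216 to mt-Co1 was not seen as a gain of mt-Co1. The cause of the difference was not tested. Whether a difference of these 3 libraries, technical or not, also bears on other calls of KO against WT after 5-FU was not tested either.

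Genes of the Y chromosome were detected in all 13 libraries, with Eif2s3y between 1312 and 2476, Ddx3y between 276 and 937, Kdm5d between 268 and 655, and Uty between 83.4 and 535. Xist is absent from the table.

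The spread between libraries was lowest in the KO group after 5-FU, with a median SD over genes of 0.182 on the log2 scale. It was 0.247 in WT after 5-FU, 0.250 in untreated KO and 0.302 in untreated WT. The value of WT after 5-FU takes the nearly alike A3 and D4 as separate, which makes it too small if they are the same sample.

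Median normalized counts of marker lists in untreated WT, untreated KO, 5-FU WT and 5-FU KO were 474, 598, 2172 and 339 for megakaryocyte and platelet genes, 325, 368, 1154 and 353 for erythroid genes, and 45.3, 53.4, 123 and 14.6 for neutrophil genes. For the monocyte and macrophage genes they were 149, 46.2, 84.2 and 122, and for B cell genes 7.10, 5.76, 45.5 and 11.0.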
